A study of Homo sapiens with 12 samples.

How the data were processed

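RNA was measured on 12 Affymetrix U133 Plus 2 arrays, each hybridised with RNA from PANC-1 or AsPC-1 cells, 2 established human pancreatic cancer lines. Cells had received a scrambled control siRNA (siControl) or 1 of 2 different siRNAs against SREBP2 (siSREBP2, siRNA 1 and siRNA 2). Per the labels' protocols, transfection used Lipofectamine RNAiMAX, and after 48 h the cells were moved for 24 h to medium of pH 7.4 or pH 6.8. RNA was extracted with Isogen, and cDNA was primed with an oligo-dT primer carrying a T7 promoter, per the labels' protocols, so the measured signal weighs the 3' parts of transcripts. The labels give 8 groups by line, pH and siRNA target, with 1 array in each siControl group and 2 arrays, 1 per siRNA, in each siSREBP2 group.

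The deposited values are MAS5 signal, a probe set's intensity on a linear scale, and MAS5 is named in the submitters' processing notes without a version. The mean of the middle 96% of each array's deposited signal values was close to 100 (99.98 in every array), so the authors' table was already scaled to 1 target per array. The table held 54675 probe sets, 62 of them controls, and 7 values of 0. Detection calls were not used here. The number of arrays limits the precision, and a dim probe set's signal is mostly background.

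Probe sets were named from the platform annotation. A single gene symbol was given for 41097 probe sets, several symbols for 1801 and no symbol for 11721, and none was named from a probe set with several. Of the probe sets with 1 symbol, 41043 were matched through the gene identifier to the annotation of GRCh38.p14, and 0 symbols needed an update. Each of the 19775 genes was represented by its brightest probe set over all 12 arrays. A gene was tested when that probe set's mean signal was at or above the 40th percentile of all probe sets that were not controls (7.283), which left 13694 genes. Some genes that a reader might look for have no named probe set in the annotation used and are not analysed here. No genome was used, so no probe positions are given.

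Values were analysed as log2(signal + 2), where 2 is the 20th percentile of all values rounded to a whole number. Differences are on that scale, which understates the change of dim genes. limma 3.58.1 in R 4.3.3 fitted 1 model to all 12 arrays with a term for the cell line and 4 conditions (pH by siRNA target). The contrasts were SREBP2 knockdown averaged over pH, knockdown at each pH, low pH in siControl and in siSREBP2 cells, the interaction of pH and knockdown, and AsPC-1 against PANC-1. Effects within a line and the differences between lines came from a model with a mean for each of the 8 groups. Both siRNAs were compared on the 8 siSREBP2 arrays with each line and pH as a pair. In every comparison a gene was called at a Benjamini-Hochberg adjusted p below 0.05 from limma's moderated test, which is two-sided. A standard error (SE) accompanies each log2 difference. Nothing in the labels says that arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. For SREBF2, all probe sets that passed the filter (26408 probe sets) were also tested singly.

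Gene lists were tested with camera in limma at its preset correlation of 0.01 and again with an estimated correlation, with p adjusted over the 17 lists. The lists covered cholesterol synthesis, sterol uptake and sensing, fatty acid synthesis, sterol efflux and LXR targets, glycolysis and hypoxia, the integrated stress response, the unfolded protein response, cell cycle, interferon response, p53 target genes, proton handling, lysosome and autophagy, epithelial genes, mesenchymal genes, inflammatory genes, oxidative stress genes, and fibroblast, immune and endothelial markers. No list call held with the estimated correlation in any comparison. The lists, the tests and the naming rule were fixed before the data were examined. The rule made eligible SREBF2, the list members with the smallest p, and per comparison the 10 genes with the largest rise and the 10 with the largest fall among those that passed with the same sign in both lines (in both siRNAs for effects within a line, and in all pairs for the siRNA comparison). Where none passed, the 5 with the smallest p in a direction were eligible and said not to pass. Not all eligible genes are printed, and those printed follow that order.

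The siRNA number was checked as a pairing of the siSREBP2 arrays across line and pH. Deviations of same-numbered arrays from their group means correlated across genes at 0.137 to 0.218 in all 6 pairs of groups, above the limit of 0.1 set for pairing. A fit with the siRNA number as a block (siRNA 1 at minus 0.5, siRNA 2 at 0.5, siControl at 0) was therefore run as an alternative, and its outcome stands beside a printed result where it changed a call or moved a count by more than 1.5 times. The other alternatives were other pseudocounts (1 and 12, the median of all values), no filter and a filter at the 60th percentile, quantile normalization, the mean over a gene's probe sets, the trend and robust options of the empirical Bayes step, a mean for each group in place of the line term, and leaving out each array in turn. Leaving out both PANC-1 pH 6.8 siSREBP2 arrays was added after seeing the data. No other pair was left out for comparison, so a role of RNA quality there cannot be told apart from the loss of arrays.

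The procedure was tested on simulated data for the 13694 genes, with 100 genes changed at each of 2 sizes. At a log2 change of 1, 74 of the 100 changed genes were recovered for knockdown, 26 for low pH in siControl cells, 43 for low pH in siSREBP2 cells, 6 for the interaction, 8 for knockdown in PANC-1 and 10 for siRNA 2 against siRNA 1. At a log2 change of 2 the corresponding numbers were 92, 66, 86, 57, 61 and 77, with 3 to 7 false calls per comparison. Simulated values were each gene's mean per line plus independent noise, without the siRNA pairing described above. The recovered and false calls therefore do not cover that structure of the real arrays. The noise had the spread of the model with a line term in every comparison. Knockdown in PANC-1 and the siRNA comparison were fitted by other models, so their recovery need not match the real arrays. No pair of arrays held the same values: the highest correlation between arrays was 0.959 and at most 1.27% of values were identical. The figures were drawn with matplotlib 3.10.9 in Python 3.11.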

Results

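Gene expression was measured in PANC-1 cells, from a carcinoma of the pancreas, and AsPC-1 cells, from ascites of a pancreatic adenocarcinoma. SREBP2, encoded by SREBF2, is a membrane-bound transcription factor that activates genes of cholesterol synthesis and uptake. The design asked how its depletion and an acid medium, each alone and together, alter expression in both lines. Each combination of 2 lines, 2 pH values and 3 siRNAs was measured on 1 array, 12 in all. The median MAS5 signal lay between 11 and 12.7 on every array, and 58.9 to 63.0% of probe sets were at or above the filter signal. The first principal component, with 62.6% of the variance, separated the lines, and the next, with 10.2%, separated the pH values. The ratio of 3' to 5' signal, a sign of RNA quality, was highest on the 2 siSREBP2 arrays of PANC-1 at pH 6.8. There it was 8.50 and 8.61 for ACTB and 1.45 and 1.68 for GAPDH, against 4.90 to 8.15 and 1.04 to 1.23 on the other arrays.

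SREBF2 signal was lower in the siSREBP2 cells on nearly all arrays. The probe set 201247_at was below the matching siControl on 8 of 8 arrays, and 6 of the 8 siSREBP2 signals lay under the filter signal. With those raised to the filter signal, at most 15.6 to 42.2% of the siControl signal was left, with a median of 21.6%. Probe set 201248_s_at had 17.0 to 45.1% left (median 32.9%), also on 8 of 8 arrays, and 242748_at, with its 1 signal under the filter raised, had 51.4 to 111% (median 67.7%) and was below the control on 7 of 8. In limma's test over single probe sets, the SREBF2 probe set 201247_at fell by 2.56 on the log2 scale (SE 0.40, adjusted p = 0.0461), or by at least 1.77 with the raised signals. The other SREBF2 probe sets differed by -1.53 (SE 0.27, adjusted p = 0.0676) and -0.51 (SE 0.26, adjusted p = 0.452). At the level of genes, where 201248_s_at stands for SREBF2, the difference of -1.53 (SE 0.26) had an adjusted p of 0.0504, and of 0.0485 with the siRNA number as a block. It passed with the median pseudocount (adjusted p = 0.0124), the stricter filter (0.0192), quantile normalization (0.0494), the trend and robust options (0.0131) and without siRNA 2 of AsPC-1 at pH 6.8 (0.039), and the range with single arrays left out was 0.039 to 0.199. The SREBF2 difference was -1.52 at pH 7.4 and -1.55 at pH 6.8. The siRNAs differed by -0.25 (siRNA 2 minus siRNA 1, adjusted p = 0.601), and low pH in siControl cells gave a SREBF2 difference of 0.38 (adjusted p = 0.703).

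**Figure D1:**
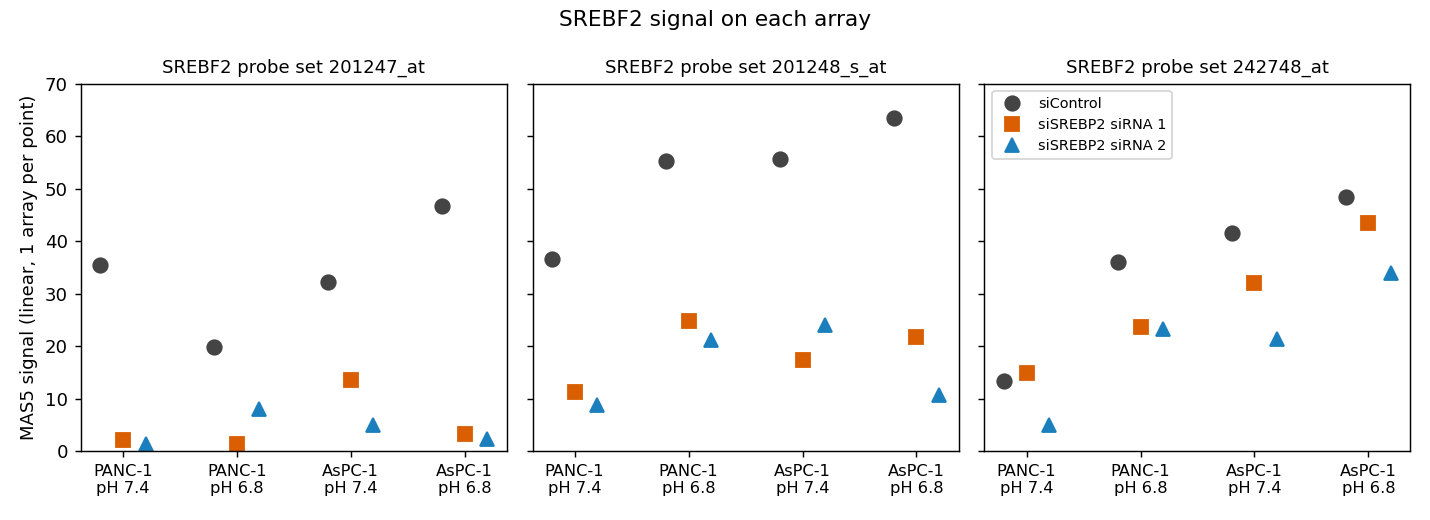
SREBF2 MAS5 signal (linear, y axis) on each of the 12 arrays by cell line and pH (x axis), in a panel for each of 3 probe sets; every point is 1 array. For 201247_at the siControl arrays lie between 19.9 and 46.8, and the siSREBP2 arrays between 1.4 and 13.6.

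In siSREBP2 cells MSMO1 and SC5D, both of cholesterol synthesis, were lower and a larger set of genes was higher than in siControl cells. The 4 siControl arrays share a scrambled siRNA, so an effect of its sequence cannot be told apart from one of knockdown. With the siRNA 2 arrays taken as control in place of these, 224 genes passed, against 50 here. Of 13694 genes tested, 48 rose and 2 fell over both lines and both pH values (8 siSREBP2 against 4 siControl arrays). MSMO1, a methylsterol oxidase, fell by 0.99 on the log2 scale (SE 0.13, adjusted p = 0.0247), and SC5D, a sterol desaturase of the same pathway, fell by 0.80 (SE 0.12, adjusted p = 0.0355). SLC36A1, a proton-coupled amino acid transporter of lysosomes, rose by 1.62 (SE 0.23), a fold of 3.08. The receptor tyrosine kinase MET rose by 1.53 (SE 0.25), and WWTR1, the transcriptional coactivator TAZ, by 1.40 (SE 0.17). Among the 10 largest rises were also LUARIS, a long noncoding RNA (1.55), MCFD2, a cargo receptor of the secretory pathway (1.36), the collagenase MMP1 (1.32), NRBF2, a subunit of an autophagy lipid kinase complex (1.32), MEI1 (1.32), the mitochondrial phosphatase PTPMT1 (1.25) and TMEM65 (1.13). LUARIS and MEI1 were dim, with mean signals of 7.87 and 11.1. MET, WWTR1 and MCFD2 each had another probe set with the opposite sign, none of which passed.

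Of 20 listed cholesterol synthesis genes 15 were measured, of which 2 fell, 13 did not pass and 0 rose. Adjusted over the list alone, 8 fell, including ACAT2 (-0.90, adjusted p = 0.0902 over all genes and 0.025 with the siRNA number as a block) and SQLE, squalene epoxidase (-0.77, 0.132 and 0.0486). IDI1 (-0.92, 0.157 and 0.0284) also passed only with the block. The list's median difference was -0.43 with 13 of 15 members negative, and as a set it stood below other genes (camera adjusted p = 1.95e-10, adjusted p = 0.374 with an estimated correlation). The 7 measured genes of sterol uptake and sensing included no call, and 1 adjusted over the list alone, TMEM97 (-0.77). Fatty acid synthesis was alike, with 0 of 13 and, adjusted over the list alone, 1, the elongase ELOVL5 (-0.73, adjusted p = 0.104 over all genes and 0.0336 with the block). In the unfolded protein response list 1 of 15 genes rose, SEL1L of the endoplasmic reticulum degradation machinery (0.80, SE 0.10, adjusted p = 0.0205), and 3 adjusted over the list alone, with DNAJC3 (0.46) and PDIA4 (0.65). None of 24 cell cycle genes passed, although 21 lay below 0 and the list stood below other genes as a set (camera adjusted p = 8.2e-05, adjusted p = 0.617 with an estimated correlation). MCM7, a helicase subunit, was lower adjusted over the list alone (-0.61). Of 15 interferon response genes 0 passed and 1 did adjusted over the list alone, IFI44 (0.88). As a set they stood above other genes (camera adjusted p = 0.0458), but not with an estimated correlation (adjusted p = 0.617) or with the siRNA number as a block (adjusted p = 0.0519). Adjusted over the list alone, CDKN1A (0.65) was higher among 11 p53 target genes and SNAI2 (0.84) among 8 mesenchymal genes, and 0 of either list passed over all genes. The other 9 lists had 0 calls, also adjusted over the list alone, and their smallest camera adjusted p was 0.165, for the inflammatory genes.

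At an unadjusted p below 0.05 there were 1908 genes in limma's test of knockdown, against 685 by chance. With the siRNA number as a block, 122 genes passed, 82 higher and 40 lower, and they included all 50. Of the 72 added, 31 had opposite signs with the 2 siRNAs or a difference from siControl that with 1 siRNA was under 50% of that with the other. The weaker was siRNA 1 in 29 of these, and 0 of the 50 were of this kind. Without the block a difference between the siRNAs adds to a gene's spread, so a gene of this kind could hardly pass there. PPP1CA, NDUFAF2, ATAD1 and IMPA1 were among the 31, with 0.12, -0.12, 0.03 and -0.07 with siRNA 1 and -2.83, -1.92, -1.72 and -1.70 with siRNA 2. The count was 0 without the filter on dim genes and with a mean fitted for each group, 12 with probe sets averaged, 84 with the median pseudocount, 118 with the stricter filter and 167 with the trend and robust options. With single arrays left out it was 0 without siControl, siRNA 1 or siRNA 2 of PANC-1 at pH 6.8, siControl or siRNA 2 of PANC-1 at pH 7.4, or siRNA 1 of AsPC-1 at pH 7.4, it was 6 and 7 without the siControl arrays of AsPC-1 at pH 6.8 and pH 7.4, and it was 14 to 23 without any of the other 4. Without both PANC-1 pH 6.8 siSREBP2 arrays, whose 3' to 5' ratios were highest, no gene passed, which cannot be told apart from the loss of arrays.

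At pH 6.8 alone, knockdown raised 3 genes and lowered none, and at pH 7.4 alone no gene passed. The genes at pH 6.8 were the pseudogene CASTOR3P (2.27, SE 0.25), the protocadherin PCDHB14 (1.82, SE 0.19) and CARMIL1, a regulator of actin capping (1.74, SE 0.20). All were dim, with mean signals of 17.4, 10.6 and 9.81, so the sizes of these rises are uncertain. With the siRNA number as a block none of them passed. CARMIL1 and CASTOR3P also fell at low pH in siControl cells, a comparison that uses the same siControl arrays at pH 6.8. The rises and falls of these genes are therefore not separate results. The lowest p among lower genes at pH 6.8 belonged to MSMO1 (-1.42, adjusted p = 0.0759), followed by ADORA1 (-1.67), C6orf15 (-2.26) and SC5D (-0.95). At pH 7.4 the higher genes with the smallest p were BAIAP2L2 (1.98), HCN2 (1.61), C7orf13 (1.02), PPP1R37 (1.18) and PTPMT1 (1.28), and the lower ones were CARMIL1 (-0.96), TCP10L (-1.37), MAPKAP1 (-0.76), WDR90 (-0.76) and CFAP52 (-1.23), none of which passed. Cholesterol synthesis genes stood below other genes at both pH values. Their median was -0.62 at pH 6.8, where 8 of 15 passed adjusted over the list alone (camera adjusted p = 3.19e-11, adjusted p = 0.339 with an estimated correlation). At pH 7.4 it was -0.29, with 0 of 15 adjusted over the list alone (camera adjusted p = 0.000311, adjusted p = 0.473 with an estimated correlation). The interaction tested below is the difference between the knockdown effects at each pH, on the same arrays. Cell cycle genes also stood below other genes as a set at pH 7.4 (median -0.22, camera adjusted p = 0.00189, adjusted p = 0.506 with an estimated correlation) and at pH 6.8 (median -0.33, camera adjusted p = 0.000948, adjusted p = 0.75 with an estimated correlation), with 0 of 24 adjusted over the list alone at either. The cell cycle medians were -0.35 in PANC-1 and -0.08 in AsPC-1 at pH 7.4, and -0.53 and -0.11 at pH 6.8, where the PANC-1 siSREBP2 arrays had the highest 3' to 5' ratios. At pH 7.4 the interferon response (median 0.28, camera adjusted p = 0.00307), the unfolded protein response (0.04, 0.0265), oxidative stress genes (0.15, 0.0265) and inflammatory genes (0.41, 0.0396) stood above other genes. Adjusted over the list alone, SEL1L (0.71) and DNAJC3 (0.53) passed, and no member of the other 3 lists did. Their adjusted p with an estimated correlation was 0.473, 0.512, 0.473 and 0.512, and the inflammatory genes' adjusted p was 0.0541 with the siRNA number as a block. Unadjusted p fell below 0.05 for 761 genes at pH 7.4 and 1541 at pH 6.8 in limma's test. The count at pH 7.4 was 3 with the trend and robust options and 1 without the AsPC-1 pH 7.4 siControl array. The count at pH 6.8 was 0 with the siRNA number as a block, without the filter, with the stricter filter, with a mean for each group, or without both siSREBP2 arrays of PANC-1 at pH 6.8, and 43 with the trend and robust options. With single arrays left out it was 8 without the siControl array of PANC-1 at pH 7.4 or of AsPC-1 at either pH, 1 and 2 without siRNA 1 and siRNA 2 of AsPC-1 at pH 6.8, and 0 without any of the other 7.

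Low pH in siControl cells raised 76 genes and lowered 227 (2 arrays at each pH, 1 per line). The probe set that stands for CDCP1, which encodes a transmembrane glycoprotein linked to Src signalling, rose by 4.81 (SE 0.55, adjusted p = 0.009), a fold of 28.1, while another CDCP1 probe set differed by -0.69. The first, 1554110_at, read 34.7 in PANC-1 and 45.4 in AsPC-1 siControl cells at pH 7.4. The other, 218451_at, read 578.7 and 549.9 there, so 1554110_at stands for CDCP1 only through its pH 6.8 signals. For PCF11, a factor of mRNA 3' end cleavage, 227622_at rose by 1.97 (SE 0.19) and 203378_at differed by -0.72, so the gene's direction is not settled. CNST, of connexin trafficking, rose by 2.15 (SE 0.38), and OSGIN1, an oxidative stress response gene, by 2.10 (SE 0.43). The other largest rises were in dim genes, LY6G6C (2.37), LOC105376689 (2.33), the sodium channel gene SCN8A (2.24), FKBP6 (2.21), SEMA5B (2.15) and the ion channel gene HCN2 (2.08), with mean signals of 7.74 to 15.1. Brighter genes among the largest falls were the BMP receptor BMPR2 (-2.32), the centrosomal genes ALMS1 (-2.34) and CEP128 (-2.57), VPS13B, of Golgi membrane traffic (-2.52), and the anthrax toxin receptor ANTXR1 (-2.53). ANKRD18A (-2.94), TBC1D19 (-2.94), ADM5 (-2.65), CARMIL1 (-2.52) and CASTOR3P (-2.43) also fell and had mean signals of 8.25 to 17.4. A dim signal is mostly background, so the sizes of the rises and falls of genes this dim are uncertain. SCN8A, CNST, HCN2, PCF11, CEP128, ANTXR1, VPS13B and BMPR2 each had at least 1 other probe set with the opposite sign, none of which passed.

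Of 15 cholesterol synthesis genes 2 rose in siControl cells at low pH, MSMO1 (1.64, SE 0.22, adjusted p = 0.0127) and HMGCS1, the synthase that makes HMG-CoA (1.62, SE 0.34, adjusted p = 0.0453), and 13 did not pass. Adjusted over the list alone, 5 rose, with SQLE (1.08, adjusted p = 0.103 over all genes and 0.0474 with the siRNA number as a block), and 1 fell, PMVK (-0.89). IDI1 (1.29, adjusted p = 0.125) passed with the block (0.0285). The list stood above other genes (median 0.36, camera adjusted p = 0.00109, adjusted p = 0.367 with an estimated correlation). Sterol uptake and sensing genes, 0 of 7 called and 3 adjusted over the list alone, also stood above (median 0.76, camera adjusted p = 0.0185), led by the sterol sensor INSIG1 (1.69, adjusted p = 0.0843, and 0.0486 with the block) and the cholesterol transporter genes NPC2 (0.81) and NPC1 (0.76). In the unfolded protein response list 1 of 15 rose, the chaperone gene HSPA5 (1.18, SE 0.21, adjusted p = 0.0281), and 6 adjusted over the list alone, with HSP90B1 (0.95, adjusted p = 0.0543 over all genes and 0.0161 with the block). That list's median was 0.47 (camera adjusted p = 1.93e-05). Oxidative stress genes gave 2 rises of 11, HMOX1, heme oxygenase (1.65, SE 0.33, adjusted p = 0.0411), and OSGIN1, and 6 adjusted over the list alone (median 0.60, camera adjusted p = 1.93e-05). Lysosome and autophagy genes had 0 of 15 calls and 3 adjusted over the list alone, MAP1LC3B (0.74), GABARAPL1 (1.28) and CTSL (0.73), and stood above other genes (camera adjusted p = 0.0153). For these last 4 lists the adjusted p was 0.205 with an estimated correlation. The replication helicase gene MCM3 fell (-1.18, SE 0.24, adjusted p = 0.0443) as 1 of 24 cell cycle genes, with 3 lower adjusted over the list alone. Among 8 proton handling genes 0 passed, and adjusted over the list alone the bicarbonate exchanger SLC4A2 (-0.87) and the carbonic anhydrase CA12 (-1.16) were lower. The interferon response had 0 calls of 15 and 1 adjusted over the list alone, IRF9 (0.75). Epithelial genes had 0 of 11, also adjusted over the list alone, with KRT19 at -1.03 and a camera adjusted p of 0.0787. The other 8 lists had 0 calls, also adjusted over the list alone, among them glycolysis and hypoxia (median -0.11) and the fibroblast, immune and endothelial markers (median 0.28).

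In limma's test of low pH in siControl cells, 2508 genes had an unadjusted p below 0.05, and each pH had only 2 siControl arrays. The count fell to 0 and 2 without the PANC-1 siControl array at pH 7.4 and pH 6.8, to 27 and 74 without the AsPC-1 siControl array at pH 7.4 and pH 6.8, and to between 137 and 203 without any siSREBP2 array, which lend their spread to the test. It was 60 without the filter on dim genes, 48 with probe sets averaged, 101 with a mean for each group, 549 with the stricter filter, 590 with the trend and robust options and 192 without both PANC-1 pH 6.8 siSREBP2 arrays.

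Low pH in siSREBP2 cells raised 395 genes and lowered 815 (4 arrays at each pH). The CDCP1 probe set 1554110_at rose by 5.29 (SE 0.39, adjusted p = 0.000593), a fold of 39.2. The CDCP1 probe set 218451_at, the brighter of these at pH 7.4, fell by 0.64 in a test over single probe sets. Larger rises among bright genes included NDST1, a heparan sulfate enzyme (1.99, SE 0.24), CNST (1.91), NBPF20 (1.86), PPFIBP1, a liprin (1.84), and the cytokine receptor OSMR (1.80), and for OSMR another probe set had -1.81 and the mean of its probe sets -0.27. At pH 7.4 that other OSMR probe set was the brighter in both lines, so the direction of OSMR is not settled. NDST1, CNST, PPFIBP1 and CEP128 each had at least 1 other probe set with the opposite sign, none of which passed. The other leading rises were C7orf57 (2.24), NF1 (2.04), SPRR4 (2.04) and TRPC2 (2.03), with mean signals of 9.22 to 29.0. BMPR2 fell by 1.93 (SE 0.23), CEP128 by 2.41, KRT80, a keratin gene, by 1.98, KIAA1549L by 1.97 and GIT2, an ARF GTPase-activating protein gene, by 2.06, and for GIT2 another probe set had 1.06. TBC1D19 (-2.71), PCDH18 (-2.45), ARHGEF39 (-2.15), ADORA1 (-2.03) and INSYN1 (-2.00) also fell, with mean signals of 10.6 to 29.9.

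**Figure D2:**
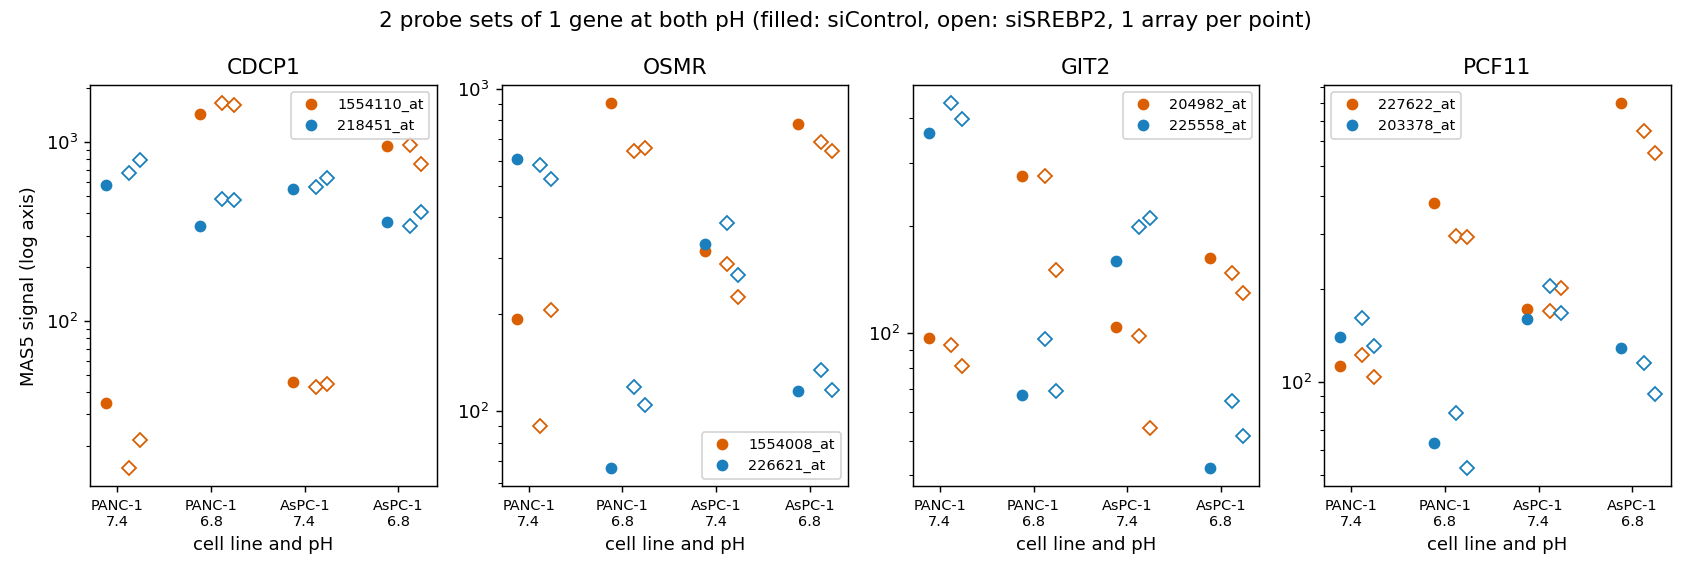
MAS5 signal (log axis) of 2 probe sets each of CDCP1, OSMR, GIT2 and PCF11 by cell line and pH (x axis); filled circles are siControl arrays, open diamonds siSREBP2 arrays, and each point is 1 array. In PANC-1 siControl cells CDCP1 probe set 1554110_at went from 34.7 at pH 7.4 to 1439.4 at pH 6.8, and 218451_at from 578.7 to 340.

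Members of several stress response lists rose in siSREBP2 cells at low pH, where the PANC-1 arrays had the highest 3' to 5' ratios. In the unfolded protein response list 4 of 15 rose and 7 adjusted over the list alone, with HSPA5 (1.25, SE 0.15, adjusted p = 0.00298) and HSP90B1 (0.95, SE 0.15, adjusted p = 0.00853). The list stood above other genes (median 0.35, camera adjusted p = 2.75e-05, adjusted p = 0.417 with an estimated correlation). Among oxidative stress genes 4 of 11 rose and 7 adjusted over the list alone, with AKR1C1 (0.96), OSGIN1 (1.63) and HMOX1 (1.08) (median 0.49, camera adjusted p = 0.000194, adjusted p = 0.393 with an estimated correlation). The integrated stress response list had 2 rises of 20, over all genes and adjusted over the list alone, the transcription factor genes DDIT3 (1.34) and CEBPB (0.61). Lysosome and autophagy genes had 3 of 15, GABARAPL1 (1.37), MAP1LC3B (0.64) and CTSL (0.60). Adjusted over the list alone, 4 rose and 1 fell. Both lists had a camera adjusted p of 0.037, and an adjusted p of 0.725 and 0.417 with an estimated correlation. Cholesterol synthesis genes went both ways, with MSMO1 up (0.79, SE 0.16, adjusted p = 0.0163), TM7SF2, a sterol reductase gene, down (-0.75, SE 0.18, adjusted p = 0.0343), and 13 of 15 not past the test (median 0.21, camera adjusted p = 0.408). Adjusted over the list alone, 2 rose and 2 fell. INSIG1 (1.40) and NPC1 (0.78) rose among 7 sterol uptake and sensing genes, also adjusted over the list alone. Of 24 cell cycle genes 3 fell, CDC45 (-1.20), MCM3 (-0.96) and FOXM1 (-0.75), and adjusted over the list alone 6 fell and 2 rose. SLC4A2 fell by 1.08 (SE 0.16) as 1 of 8 proton handling genes, TP53I3 fell (-1.41) and GDF15 rose (1.45) among 11 p53 target genes, KRT19 fell (-1.08) among 11 epithelial genes and ICAM1 fell (-1.07) among 12 inflammatory genes. NDRG1 (0.63) and HK2 (0.94, adjusted p = 0.045, and 0.0522 with the siRNA number as a block) rose among 18 genes of glycolysis and hypoxia. These counts were the same adjusted over the list alone, except 2 for the epithelial genes. The 5 lists of fatty acid synthesis, sterol efflux and LXR targets, interferon response, mesenchymal genes and fibroblast, immune and endothelial markers had 0 calls, also adjusted over the list alone.

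Of the 76 genes raised by low pH in siControl cells 65 also rose in siSREBP2 cells, and of the 227 lowered 190 also fell, against 2.19 and 13.5 for independent lists. The compared arrays were separate, although all arrays share the estimate of spread. In limma's test of low pH in siSREBP2 cells, 3670 genes had an unadjusted p below 0.05, and 464, 588, 607, 573, 700 and 769 genes passed without, in turn, siRNA 1 and siRNA 2 of PANC-1 at pH 7.4, siRNA 1 and siRNA 2 of PANC-1 at pH 6.8, siRNA 1 of AsPC-1 at pH 7.4 and siRNA 1 of AsPC-1 at pH 6.8. The count was 602 without the filter on dim genes, 788 with probe sets averaged, 1859 with the trend and robust options, and 95 without both PANC-1 pH 6.8 siSREBP2 arrays, whose 3' to 5' ratios were highest. With no other pair left out, the drop to 95 cannot be told apart from the loss of those arrays.

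In the test of the interaction (low pH difference in siSREBP2 minus that in siControl cells), cholesterol synthesis genes stood below other genes as a set, and 1 single gene passed. The interaction is also the knockdown difference at pH 6.8 minus that at pH 7.4, so it is not separate evidence from those differences. The median interaction of the 15 genes was -0.30, with 13 negative (camera adjusted p = 0.00313, adjusted p = 0.603 with an estimated correlation). The list's median low pH difference was nearly the same in siControl and siSREBP2 cells of PANC-1 (0.27 and 0.25) and was 0.44 and 0.03 in AsPC-1. None of the 15 passed, over all genes or adjusted over the list alone, and the members with the smallest p were MSMO1 (-0.85, SE 0.27), HMGCS1 (-1.08, SE 0.41), IDI1, of isoprenoid synthesis (-1.08, SE 0.48), and SQLE (-0.73, SE 0.37). No other list passed, and 0 of their members did adjusted over the list alone. The only gene that passed was CARMIL1 (2.70, SE 0.29, adjusted p = 0.0493, and 0.0795 with the siRNA number as a block). Its mean signal of 9.81 was close to the filter signal of 7.283, so the size of 2.70 is uncertain. Those with the smallest p in the other direction were BAIAP2L2 (-2.63), HCN2 (-2.06), PPP1R37 (-1.28), SMTNL1 (-2.43) and ADORA1 (-1.61), none of which passed. In limma's test 425 genes had an unadjusted p below 0.05, fewer than the 685 of chance, and 0 passed with the siRNA number as a block, with another pseudocount or filter, with the trend and robust options, with a mean for each group, or without both PANC-1 pH 6.8 siSREBP2 arrays, whose 3' to 5' ratios were highest. With single arrays left out, 2 genes passed without the AsPC-1 pH 6.8 siControl array and 0 without any of the other 11. The cholesterol list's median was -0.09 without the PANC-1 pH 7.4 siControl array and -0.19 without siRNA 1 of PANC-1 at pH 7.4.

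**Figure D3:**
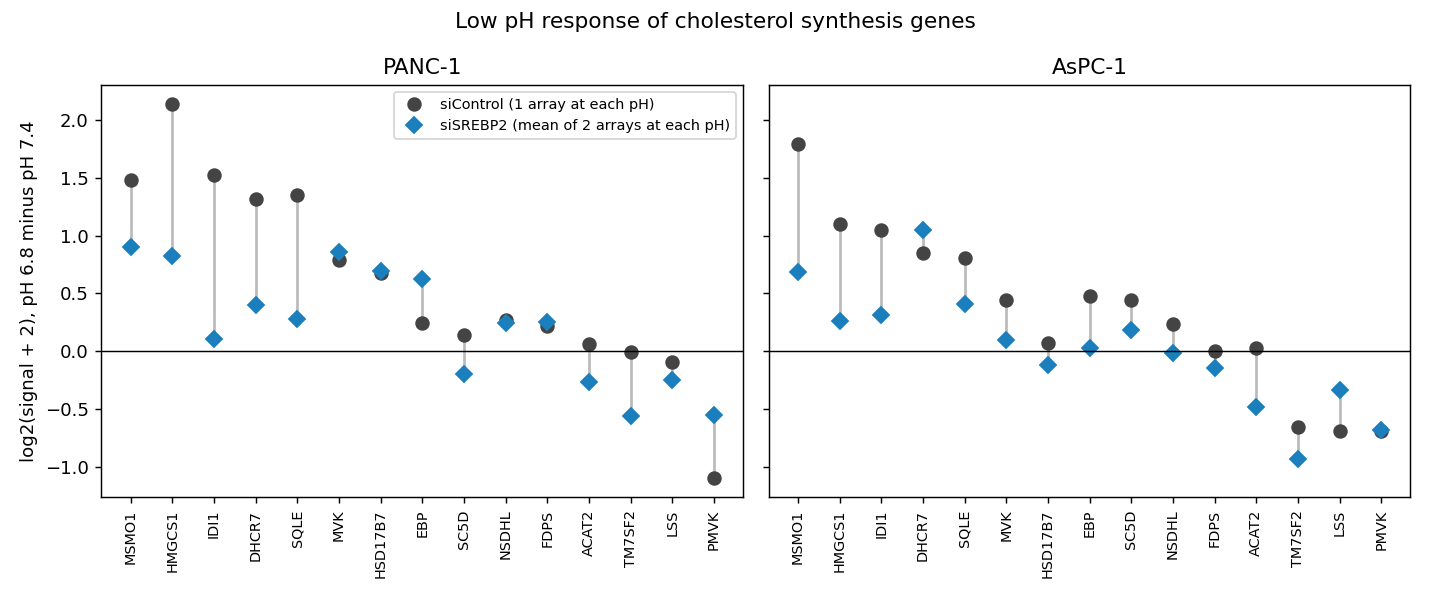
Difference between pH 6.8 and pH 7.4 in log2(signal + 2) (y axis) of the 15 cholesterol synthesis genes (x axis) in PANC-1 and AsPC-1; circles are siControl (1 array at each pH) and diamonds the mean of the 2 siSREBP2 arrays at each pH, with no error bar because siControl has 1 array. For HMGCS1 the siControl value is 2.14 in PANC-1 and 1.10 in AsPC-1, against 0.83 and 0.26 in siSREBP2 cells.

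Within each line, knockdown changed no gene past the threshold, and no gene passed the test of a difference between lines. In PANC-1 the smallest p belonged to GABRD, a GABA receptor subunit gene (2.40, SE 0.17, adjusted p = 0.0524) and MET (1.93) among higher genes, and to TMEM97, a sterol-regulated membrane protein gene (-1.14, adjusted p = 0.0908), CFAP45 (-1.56) and ARHGEF39 (-1.50) among lower ones. In AsPC-1 they were POM121L2 (1.67, adjusted p = 0.114), RHBDL2 (2.02) and BEAN1 (2.11), and the transporter gene SLC43A3 (-1.77), PON3 (-2.07) and SLC15A3 (-1.43). The integrated stress response list differed between lines in its answer to knockdown, with a median of 0.50 (AsPC-1 minus PANC-1) and 19 of 20 members positive (camera adjusted p = 1.02e-06, adjusted p = 0.577 with an estimated correlation). None passed over all genes, and adjusted over the list alone 2 did, CHAC1 (1.61, SE 0.26) and TRIB3 (1.01, SE 0.21). Cell cycle genes differed likewise (median 0.27, camera adjusted p = 0.00125, adjusted p = 0.577 with an estimated correlation), with 0 of 24 adjusted over the list alone. Sterol uptake and sensing (camera adjusted p = 0.196, and 0.0491 with the siRNA number as a block) and inflammatory genes (0.196 and 0.0226) passed only with the block, and with an estimated correlation, without the block, their adjusted p was 0.577 and 0.853. In the response to low pH the inflammatory genes had a median line difference of 0.55 (camera adjusted p = 0.0114, adjusted p = 0.655 with an estimated correlation), with 0 of 12 past the test and 1 adjusted over the list alone, the chemokine gene CXCL2 (1.89, SE 0.25). The PANC-1 siSREBP2 arrays at pH 6.8, which enter each of these line differences, had the highest 3' to 5' ratios. In limma's tests the genes with an unadjusted p below 0.05 numbered 2007 for knockdown in PANC-1, 1069 in AsPC-1, 857 for the line difference in knockdown and 1596 for that in low pH. In PANC-1 the count was 232 with the trend and robust options, 43 with the stricter filter, 18 with the median pseudocount, 2 with quantile normalization and 1 with the pseudocount of 1. In AsPC-1 it was 2 with the pseudocount of 1 and 1 with the stricter filter, and for the line difference in low pH it was 5 with the trend and robust options and 1 with the median pseudocount.

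The siRNAs against SREBP2 differed in 4 genes, all lower with siRNA 2 in each of the 4 pairs. PPP1CA, a catalytic subunit of protein phosphatase 1, differed by -2.95 (SE 0.12, adjusted p = 0.0322), with a signal of 89.7 to 117.1 with siRNA 2, against 554.7 to 968.1 with siRNA 1 and 667.7 to 850.4 in siControl cells. NDUFAF2, an assembly factor of respiratory complex I, differed by -1.80 (SE 0.11), ATAD1, a mitochondrial outer membrane ATPase gene, by -1.75 (SE 0.11) and IMPA1, an inositol phosphatase gene, by -1.63 (SE 0.10, adjusted p = 0.0469). Higher with siRNA 2, but not past the test, were EIF5A2 (1.61, adjusted p = 0.0642), TGFBR2 (1.31), TMEM217 (1.49), FAM238B (1.54) and TPSG1 (1.10). Unadjusted p was below 0.05 for 2389 genes. The count was 0 without any 1 of the 8 arrays or without the filter, 1 with probe sets averaged or a pseudocount of 1, 2 with quantile normalization, 28 without the pairs as a block, 315 with the median pseudocount, 458 with the stricter filter and 1058 with the trend and robust options.

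The lines differed far more than any treatment, with 3370 genes higher and 4046 lower in AsPC-1 than in PANC-1 (6 arrays per line). The DNA sensor IFI16, above the filter signal in both lines, was higher in AsPC-1 by 4.20. For the other genes named here the dimmer line lay under the filter signal on 1 to 6 of its 6 arrays, so the size of the difference is a lower bound, with those signals raised to 7.28. BCHE, butyrylcholinesterase, was higher by at least 4.41, the tetraspanin TSPAN8 by 4.65, RARRES1 by 3.31, the aldo-keto reductase AKR1C3 by 3.90, the intestinal cadherin CDH17 by 4.26, CEACAM6 by 4.24 and LUM, lumican, by 2.77. LDHB, a lactate dehydrogenase subunit gene, was lower in AsPC-1 by at least 9.03, with an AsPC-1 signal of 0.3 to 1.7. BASP1 was lower by at least 7.19, BNIP3, a mitophagy receptor gene, by 7.06, DKK3, of the Wnt antagonist family, by 7.33, the chemokine gene CCL2 by 6.52, PLOD2, a collagen lysyl hydroxylase gene, by 6.92, and the matrix protein gene SPARC by 6.53. AKR1C3, LUM, CCL2 and SPARC are also members of the oxidative stress, marker, inflammatory and mesenchymal lists. The adjusted p of limma's test reached 8.81e-11, and the count was 6700 to 7129 with single arrays left out.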

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

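The 3 tests of explanations for the cholesterol synthesis pattern were chosen after the result was seen. The other results in this part are given as values only.

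In the planned camera test at the preset correlation, the low pH response of cholesterol synthesis genes differed between siControl and siSREBP2 cells (median interaction -0.30). With an estimated correlation the list did not pass (adjusted p = 0.603), and no single member passed. The list's median low pH difference itself was 0.27 and 0.25 in siControl and siSREBP2 cells of PANC-1, against 0.44 and 0.03 in AsPC-1. A single outlying siControl array is argued against as the whole cause, since the list's median lay at the 0.16 percentile of 10000 random lists matched on signal in PANC-1 (-0.34) and at the 0.02 percentile in AsPC-1 (-0.27), although without the PANC-1 pH 7.4 siControl array the overall median was -0.09. Lower RNA quality of the PANC-1 pH 6.8 siSREBP2 arrays is argued against as the whole cause by the same AsPC-1 percentile of 0.02, in which those arrays have no part, and the AsPC-1 pH 6.8 ratios were 5.64 and 5.49 in siSREBP2 against 6.05 in siControl cells for ACTB and 1.17 and 1.23 against 1.23 for GAPDH. Loss of SREBP2 stays open as a candidate explanation: the medians were -0.38 and -0.22 with siRNA 1 and siRNA 2 in PANC-1 and -0.24 and -0.35 in AsPC-1, but siRNA 2 in PANC-1 lay at the 3.17 percentile, short of the limit of 2.5. Random lists ignore that these genes vary together, the p with an estimated correlation was 0.106 before adjustment, and each siControl value rests on 1 array per line and pH. The list's rise at low pH in siControl cells uses those same arrays, so it and the interaction are not separate results.

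CARMIL1 stood out by its own test of interaction, at 2.70, and its signal was 18.1 and 2.3 in siControl cells of PANC-1 at pH 7.4 and pH 6.8. The 2.3 lay under the filter signal of 7.283, so the size of 2.70 is uncertain. That array also enters the CARMIL1 fall at low pH in siControl cells and its rise after knockdown at pH 6.8, so these are not separate results. The integrated stress response list differed between the lines in its response to knockdown by a median of 0.50, being -0.29 in PANC-1 and 0.17 in AsPC-1. The cell cycle list differed between lines by 0.27 in the same comparison, being -0.43 in PANC-1 and -0.09 in AsPC-1. The inflammatory genes differed between lines in their response to low pH by a median of 0.55. None of these line differences passed camera with an estimated correlation (adjusted p = 0.577, 0.577 and 0.655 in the order given). The PANC-1 siSREBP2 arrays at pH 6.8, which enter each of them, had the highest 3' to 5' ratios.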

How the results depend on the processing

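The setting that leaves out both PANC-1 pH 6.8 siSREBP2 arrays was chosen after seeing the data, and the others were planned. Values are numbers of genes called unless said otherwise, and the cause of a change was not tested except where the setting itself changes the number of genes or arrays. With a pseudocount of 1 the interaction had 0 genes, knockdown in PANC-1 had 1 and in AsPC-1 2, and siRNA 2 against siRNA 1 had 1. With the median pseudocount, knockdown over both lines had 84, the interaction 0, knockdown in PANC-1 18, the line difference in low pH response 1 and the siRNA comparison 315, and SREBF2 passed at -1.14 (adjusted p = 0.0124). Without the filter, which adds dim genes to the adjustment, knockdown had 0, low pH 60 in siControl and 602 in siSREBP2 cells, and the interaction, knockdown at pH 6.8 and the siRNA comparison 0. With the 60th percentile filter, which tests fewer genes, knockdown had 118, low pH in siControl cells 549, the interaction and knockdown at pH 6.8 had 0, knockdown in PANC-1 43 and in AsPC-1 1, and the siRNA comparison 458, and SREBF2 passed at -1.53 (adjusted p = 0.0192). With quantile normalization knockdown in PANC-1 had 2 and the siRNA comparison 2, and SREBF2 passed at -1.55 (adjusted p = 0.0494). With probe sets averaged, knockdown had 12, low pH 48 in siControl and 788 in siSREBP2 cells and the siRNA comparison 1, and OSMR reversed in siSREBP2 cells at low pH, to -0.27, where that setting averages probe sets of opposite sign. With the trend and robust options knockdown had 167, low pH 590 and 1859, the interaction 0, knockdown at pH 7.4 3 and at pH 6.8 43, knockdown in PANC-1 232, the line difference in low pH response 5 and the siRNA comparison 1058, and SREBF2 passed at -1.53 (adjusted p = 0.0131).

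With the siRNA number as a block, knockdown had 122 genes, the interaction 0 and knockdown at pH 6.8 0, and SREBF2 passed at -1.53 (adjusted p = 0.0485). It kept 284 of 303 genes for low pH in siControl cells, 1185 of 1210 in siSREBP2 cells and 7335 of 7416 between the lines, and these counts moved to 390, 1551 and 7665. Where the report prints a gene's value for a comparison and the block changed its call there, the report says so beside it. Calls of named or listed genes also changed in comparisons for which the report does not print them, CDC45 (adjusted p 0.0842 to 0.0432) and KIAA1549L (0.0575 to 0.0309) for low pH in siControl cells among them. Without the pairs as a block the siRNA comparison had 28. With a mean for each group in place of the line term, knockdown had 0, low pH in siControl cells 101, and the interaction and knockdown at pH 6.8 0. Without both PANC-1 pH 6.8 siSREBP2 arrays, which leaves fewer arrays, knockdown had 0, low pH 192 in siControl and 95 in siSREBP2 cells, and the interaction and knockdown at pH 6.8 0.

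Leaving out each of the 12 arrays in turn gave 0 to 23 genes for knockdown, 0 to 203 for low pH in siControl and 464 to 1128 in siSREBP2 cells, 0 to 2 for the interaction, 0 to 1 for knockdown at pH 7.4, 0 to 8 at pH 6.8, 0 to 4 for the siRNA comparison and 6700 to 7129 for the lines. Knockdown within each line and both line differences stayed at 0 in all fits that could be made, and a lone array was assumed to vary like the others. SREBF2 ranged from -1.63 to -1.38 (adjusted p 0.039 to 0.199). The cholesterol list's median ranged from -0.60 to -0.35 for knockdown, 0.26 to 0.38 for low pH in siControl cells and -0.36 to -0.09 for the interaction. For low pH in siControl cells the unfolded protein response list ranged from 0.37 to 0.61 and the oxidative stress list from 0.46 to 0.68. Each of these 5 list results kept its direction. Each also kept a camera p below 0.05 at the preset correlation, before adjustment over the lists. Whether the calls held after that adjustment was not tested. For the 137 named results of single genes, 2407 of 2965 values kept direction and side of the threshold, 510 no longer passed, 47 newly passed and 1 reversed. Between the lines 419 of 419 values were kept, against 311 of 481 for knockdown and 40 of 84 for siRNA 2 against siRNA 1. For a fold of a dim gene, signal over background is the limit, and the pseudocount sets its size.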

Other observations

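The genes named in this part were chosen after their values were seen, and the tests of explanations in this part were set before their results, except the comparison of splits that keep each siRNA together, which was chosen after.

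At low pH, probe sets of 1 gene moved in opposite directions. In siSREBP2 cells 86 of 6890 genes with at least 2 probe sets had 1 that rose and another that fell (2398 of 26408 probe sets were called), against 9 genes in siControl cells (577 called), 0 for knockdown (50 called), 0 for siRNA 2 against siRNA 1 (0 called) and 284 between the lines (12764 called). The cortactin gene CTTN, of the actin cytoskeleton, went from 170.6 to 1647.2 signal in PANC-1 siControl cells on 214073_at and from 2985 to 1992.6 on 201059_at. The CDCP1 probe set 1554110_at went from 34.7 to 1439.4 and 218451_at from 578.7 to 340. DST, a cytoskeletal linker gene, went from 59.4 to 304.6 on 204455_at and from 1452.7 to 1043.3 on 215016_x_at. PCF11 (1.53 and -0.99), the poly(A) polymerase gene PAPOLA (1.48 and -0.94) and the cleavage stimulation factor gene CSTF3 (1.35 and -1.01) were also among the 86, and no list of such factors was tested.

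RNA degradation is argued against as the whole cause. In AsPC-1 siControl cells the ACTB 3' to 5' ratio was lower at pH 6.8 than at pH 7.4 (6.05 against 8.15). The GAPDH ratio was about level there (1.23 against 1.20), yet the gap between the probe sets kept its sign in 100% of the 86 genes. With siRNA 1 and siRNA 2 of PANC-1, where both ratios rose at pH 6.8, the median gap was 2.27 and 2.39. In AsPC-1 it was 1.97 and 2.01 with these siRNAs, so a contribution of RNA quality is not excluded. Noise of dim probe sets is argued against too, since 79 of the 79 genes with both probe sets bright (100%) kept the sign of the gap in siControl cells of both lines. A change of transcript isoforms at low pH is a candidate explanation. In siControl cells the gap kept its sign in all 86 (100%), with a median of 2.06 in PANC-1 and 1.92 in AsPC-1. There the probe sets moved in opposite directions in 84 and 83. The siControl arrays are outside the difference that chose the genes, but they enter its estimate of spread and the filter. The comparison with the siRNAs adds little, because that contrast called 0 probe sets. Without probe positions a change of isoforms and retained intron sequence were not distinguished.

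Genes that rose most at low pH in a line's siControl arrays appeared to rise less after knockdown, but the same arrays serve in both values. The 200 genes with the largest rise in PANC-1 had a median interaction of -1.63 in PANC-1 and -0.13 in AsPC-1 (10.95 percentile of random lists), and those chosen in AsPC-1 had -2.06 in AsPC-1 and -0.03 in PANC-1 (37.03 percentile). This is consistent with the shared siControl arrays as the source of that pattern.

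Probe sets without a gene symbol were tested apart (5122 probe sets). Low pH in siSREBP2 cells raised 94 and lowered 81 of them, and in siControl cells it raised 2 and lowered 0.

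Other splits of the arrays were fitted for comparison. For knockdown, 2 of 81 splits that took 1 array per line and pH as control, the real one among them, gave at least the real 50 genes. The siRNA number pairs the arrays, though, and most of these splits mix siRNAs within the control group. The 3 splits that keep each siRNA together are too few for a share under 0.05, with 50 genes in the real one and 224 in the highest other. That one took the siRNA 2 arrays as control and gave several times the real count, which points to a structure of the siRNA 2 arrays. It is not excluded that the 50 genes hold a like structure of the siControl arrays. For low pH in siSREBP2 cells the real split was the only 1 of 35 with 1210 genes, and the highest other, which parted the siRNAs, gave 48. For the lines the real split was the only 1 of 100 drawn with 7416 genes, and the highest other gave 1. In the other splits for low pH and for the lines, the real difference enters the spread and lowers the counts. Those splits therefore do not gauge chance. For siRNA 2 against siRNA 1 the real split gave 4 and the highest of the others 0, and the 8 splits are too few for a share under 0.05.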
